A study of Mus musculus with 12 samples.

How the data were processed

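RNA of 4599 mouse melanoma cells was measured by sequencing in 12 libraries, 3 from each of the groups TB, PIF, DIF and Met. Per the labels' protocols, cells were isolated from tumours or lung metastases, grown on fibrillar bovine dermal collagen at 1.7 mg/ml for 24 h with 10% serum and 24 h with 1% serum, and lysed, and the RNA was purified with TRIzol and RNeasy columns. Libraries were sequenced on an Illumina instrument as paired reads of 150 bases per the labels. Per the submitters' processing notes, reads were cleaned with fastp, aligned with HISAT2 2.0.5 and assigned to genes with featureCounts 1.5.0-p3. The genome build, the annotation release and the strand setting are not given in the sources used here. Of the 56748 gene identifiers in the table, 52125 also stand in the GENCODE M21 release of GRCm38, but only 1524 have the same start and end there and 4.24% of starts lie within 1000 bases. Coordinates are therefore given as the deposited table lists them.

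The deposited values are FPKM, which the authors computed from read counts, gene length and library size. FPKM multiplied by gene length gave whole multiples of 1 step per library, at a tolerance of 0.001, which allowed the read counts to be rebuilt. They summed to 15.5 to 18.4 M reads per library, 17.6 ± 0.872 M on average (SD over 12 libraries). Median-ratio size factors computed on the deposited FPKM were 1.0053 in each library, so the FPKM had already been scaled to equal median ratios. Between 18952 and 19557 genes were above 0 in a library, 27256 in at least 1 library and 14769 in all 12. The 10 most abundant genes took 6.20 to 6.92% of reads. Mean rRNA shares were 1.51% of reads in TB, 1.27% in PIF, 1.20% in DIF and 1.42% in Met. Protein-coding genes with a symbol of Rpl or Rps and a digit took 6.13 ± 0.413%, 5.69 ± 0.306%, 6.01 ± 0.311% and 5.59 ± 0.218%. These genes were picked by symbol and are not the list of cytosolic ribosomal proteins used below.

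Genes with a mean FPKM of at least 0.5 over the 12 libraries were tested, which kept 12661 of 56748. limma 3.58.1 in R 4.3.3 was fitted to log2(FPKM + 1) with 1 mean per group, a shared spread with 8 residual degrees of freedom and an intensity trend. All 6 pairs of groups were compared, two-sided, together with a moderated F test over the 4 groups. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. Because of the added 1, fold changes of genes with low FPKM are smaller than the quotient of their means. Gene symbols, biotypes and gene lengths are those of the deposited table.

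The design, the tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. There were 29 lists, of which 23 had at least 5 tested members. They were actomyosin contractility, YAP and TEAD targets, MRTF and SRF targets, TGF-beta pathway, collagens and matrix, matrix proteases and inhibitors, integrins and focal adhesions, melanocyte differentiation, dedifferentiated and invasive melanoma state, NF-kappaB and cytokines, interferon response, JAK-STAT3 signalling, G2 and mitosis, G1 to S and replication, hypoxia and glycolysis, oxidative phosphorylation, cholesterol synthesis, ATF4 and unfolded protein response, p53 targets and chromatin modifiers, with cytosolic ribosomal proteins, mitochondrially encoded genes and heat shock and immediate early genes as signs of RNA quality. Markers of fibroblasts, leukocytes, endothelium, lung epithelium, keratinocytes, and skeletal muscle and adipocytes had under 5 tested members each and were summed as FPKM. Some genes stand in more than 1 list. Member counts in the results are of tested genes only. Melanocyte differentiation had 13 tested of 27 listed, the interferon response 23 of 49 and NF-kappaB and cytokines 22 of 41. Lists were tested with camera from limma with a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 23 lists, and again with an estimated correlation and with fry. camera asks whether a list ranks apart from the other genes, and fry whether its genes move on balance in 1 direction.

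Named genes were, for each comparison with TB, the 10 largest rises and the 10 largest falls among protein-coding calls whose 3 values all lay beyond the 3 TB values, without predicted or clone names, and 5 and 5 for the other pairs. Added were the 10 genes in each direction called in all 3 comparisons with TB with the largest smallest change, the 4 members of each list with the smallest p in each comparison with TB, the 3 most abundant markers of each other cell type, and Myl9, Myh9, Rock1, Rock2, Rhoa, Rhoc, Mitf, Tyr, Dct, Sox10, Axl, Ngfr, Xist, Ddx3y, Eif2s3y, Kdm5d and Uty. From these the text names a part. Gm46223, Gm37416, Ngef, Gm48479, Gm48480, Tmem179, Trib3, Col1a1, Col1a2, Dcn, Lum, Pecam1, Cdh5, Kdr, Tek, Sftpc, Sftpb, Scgb1a1 and Epcam lie outside this rule and were chosen after their values were seen. Reads of near-identical copies, such as the Prl2c family, Mmp1a and its neighbours and ribosomal protein pseudogenes, and of genes that overlap on opposite strands cannot be assigned with certainty.

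The alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean FPKM of at least 2, median-ratio scaling, quantile normalization, a block for the replicate number, voom from limma on the rebuilt reads, a spread from only the 2 groups compared, and leaving out each library in turn. Removal of trends with GC content and gene length was added after seeing the data, with GC content from the reference for 12431 tested genes (98.2%). The methods were tested on simulated data of the same depths with a dispersion of 0.01 and 200 changed genes. Among 100 genes changed 1.5-fold, limma found 62% and voom 83%, among 100 changed 2-fold both found 100%, and 5.26% of limma calls were unchanged genes. The fitted median folds were 1.43 and 1.81. A list shifted 1.2-fold was called by camera (adjusted p 8.7e-13) as the 1 called list of 23, and with no change simulated limma called 0 genes and camera 0 lists. Genes were drawn independently in the simulated data, whereas the correlation estimated in the real data reached 0.63 for mitochondrially encoded genes. The simulation therefore cannot show how often camera with the preset correlation calls unchanged lists of correlated genes. In the real data, splits that mixed the groups compared gave up to 14, 11 and 10 lists. The real splits of PIF, DIF and Met against TB gave 11, 10 and 7. Transcripts of Gm46223 (675 bases) and Gm37416 (318 bases) were aligned to the reference transcripts with blastn 2.17.0, keeping alignments of at least 200 bases at 85% identity. The other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No sample column was left out.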

Results

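RNA was sequenced from 12 libraries of 4599 cells, a mouse melanoma line, in 4 groups of 3 libraries. The cells had been isolated from orthotopic melanomas, in 3 groups that the labels abbreviate TB, PIF and DIF, or from melanoma lung metastases, abbreviated Met. The sources used here do not spell out these abbreviations. All isolated cells were then seeded on fibrillar bovine dermal collagen at 1.7 mg/ml, kept 24 h with 10% serum and 24 h with 1% serum, and lysed. The 4 groups therefore met 1 common substrate, and the comparisons ask which genes still differed by the tumour part the cells came from. The study's title concerns matrix topography and a memory held in the cytoskeleton and in transcription. The rebuilt number of reads assigned to genes was 15.5 to 18.4 M per library, with means of 17.7 ± 0.260 M in TB, 17.2 ± 1.46 in PIF, 17.5 ± 1.12 in DIF and 18.1 ± 0.182 in Met (SD, n = 3). Levels are given below as mean FPKM ± SD over the 3 libraries of a group, and log2 fold changes on the log2(FPKM + 1) scale with their SE. Whether the 3 libraries of a group came from different animals is not stated, so p-values measure only the spread between these samples, which may be technical.

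Gpnmb, a transmembrane glycoprotein of pigment cells and macrophages (chromosome 6, 49013480 to 49047863, plus strand), was measured at 93.5 ± 3.44 FPKM in TB, 170 ± 25.3 in PIF, 7.66 ± 1.03 in DIF and 6.57 ± 0.115 in Met. Acta2, smooth muscle actin (chromosome 19, 34218490 to 34232990, minus strand), was measured at 103 ± 2.09, 41.4 ± 9.75, 255 ± 38.3 and 172 ± 42.4 FPKM in the same order. Htra1, a secreted serine protease (chromosome 7, 130537841 to 130587390, plus strand), was measured at 1.53 ± 0.359, 2.93 ± 0.633, 34.4 ± 7.09 and 28.8 ± 3.19 FPKM. Of 12661 genes tested, 3135 (24.8%) differed among the 4 groups at an adjusted p under 0.05 in limma's moderated F test. Component 1 of a principal component analysis held 35.1% of the variance and placed PIF (−23.5 to −20.5) and TB (−7.78 to −6.47) on the side opposite to DIF (13.1 to 18.7) and Met (12.1 to 15.4). Component 2 held 16.4% and set TB (−18.1 to −12.4) apart from PIF (6.07 to 10.9) and Met (8.71 to 11.3). Across genes, correlations between libraries of 1 group were 0.986 to 0.994, those between DIF and Met 0.983 to 0.989 and those between PIF and DIF 0.967 to 0.977. Genes are not independent replicates in these correlations.

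**Figure D1:**
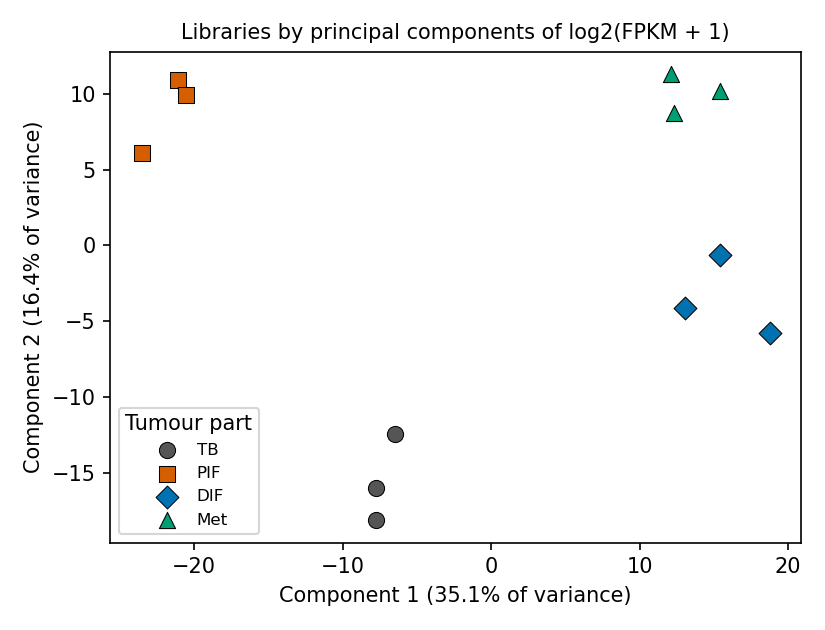
Each point is 1 of the 12 libraries, placed by principal components 1 and 2 of log2(FPKM + 1), with the share of variance on each axis. PIF lies at −23.5 to −20.5 on component 1, and DIF and Met lie at 12.1 to 18.7.

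PIF against TB asked what distinguished PIF cells from TB cells on the same collagen. PIF cells held more RNA of the prolactin family hormones Prl2c3 (89.2 ± 19.3 against 9.47 ± 3.01 FPKM; chromosome 13, 12805705 to 12814968, minus strand) and Prl2c2 (146 ± 12.8 against 26.4 ± 4.08). Reads may be shared among members of this family, so the division between these genes is uncertain. Slc7a11, the cystine and glutamate exchanger (chromosome 3, 49846975 to 50398063, minus strand), rose from 1.05 ± 0.147 to 7.66 ± 0.943 FPKM (log2 fold change 2.07, SE 0.14). Mmp10, a stromelysin, rose from 3.83 ± 0.553 to 15.1 ± 2.04 FPKM, and Nqo1, a quinone reductase, from 1.92 ± 0.225 to 9.04 ± 2.74. Fabp3, a fatty acid binding protein, fell from 27.8 ± 4.55 to 10.1 ± 1.41 FPKM, elastin (Eln) from 5.20 ± 0.498 to 1.44 ± 0.415 and periostin (Postn) from 111 ± 2.04 to 45.2 ± 13.6. limma called 1785 genes (14.1% of those tested), 952 higher and 833 lower, with Benjamini-Hochberg adjusted p of 9.6e-05 for Prl2c3, 2.4e-05 for Slc7a11 and 9.6e-05 for Fabp3. Among the calls, 63 reached a 2-fold change, 46 of them higher and 17 lower, and the median size of the log2 fold change was 0.40. The count was 993 without TB replicate 2, 958 without TB replicate 3, 1102 without PIF replicate 1 and 1132 when the spread came from the 6 libraries of these groups alone.

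Lists of contractile, serum response and mitotic genes were called lower in PIF by camera with the preset correlation. Among 47 tested genes of actomyosin contractility, 17 fell and 1 rose (21 and 4 adjusted over the list alone), with a median log2 fold change of −0.16 and a camera adjusted p of 9.3e-06 (adjusted p = 0.21 with an estimated correlation). Acta2 fell by 1.32 on the log2 scale (SE 0.19), Myl9, the regulatory myosin light chain, went from 141 ± 7.91 to 70.6 ± 10.2 FPKM, Tagln2 from 852 ± 23.2 to 577 ± 30.3 and Rhoc from 582 ± 12.2 to 445 ± 17.8. Of 26 MRTF and SRF targets, 11 fell and 0 rose in limma (13 and 0 adjusted over the list alone). The list's median was −0.27 and its camera adjusted p 9.3e-06 (adjusted p = 0.21 with an estimated correlation). Ccn2, a matricellular growth factor and YAP target, fell from 218 ± 1.23 to 99.6 ± 21.4 FPKM, and Ccn1 fell by 0.62 on the log2 scale (SE 0.12). YAP and TEAD targets as a list went both ways, 5 up and 4 down of 21 (7 and 4 adjusted over the list alone; camera adjusted p 0.71). Among 34 genes of G2 and mitosis, 16 fell and 0 rose in limma (24 and 0 adjusted over the list alone). The list had a median of −0.22 and a camera adjusted p of 1.8e-11 (adjusted p = 0.21 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, went from 114 ± 4.39 to 87.0 ± 4.38 FPKM and Bub1b, a spindle checkpoint kinase, from 28.0 ± 0.529 to 21.3 ± 1.02.

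The lists of the ATF4 and unfolded protein response, of hypoxia and glycolysis, of cholesterol synthesis and of G1 to S and replication were called higher in PIF by the same test. Among 30 genes of the ATF4 and unfolded protein response, 16 rose and 0 fell in limma (22 and 0 adjusted over the list alone). The median log2 change was 0.28, with a camera adjusted p of 7.3e-13 (adjusted p = 0.21 with an estimated correlation). Hspa5, the chaperone BiP, rose from 124 ± 2.24 to 211 ± 26.5 FPKM, Ddit3, the transcription factor CHOP, from 12.6 ± 1.23 to 20.8 ± 1.16 and the chaperone Hyou1 from 11.1 ± 0.657 to 20.2 ± 3.30. Of 29 genes of hypoxia and glycolysis, 12 rose and 1 fell (13 and 1 adjusted over the list alone). Camera gave this list, at a median of 0.26, an adjusted p of 1.9e-06 (adjusted p = 0.21 with an estimated correlation). Vegfa rose from 3.64 ± 0.132 to 7.78 ± 0.296 FPKM and the glucose transporters Slc2a1 and Slc2a3 rose by 0.81 (SE 0.13) and 0.84 (SE 0.09) on the log2 scale. Of 23 genes of cholesterol synthesis, 8 rose and 0 fell in limma (10 and 1 adjusted over the list alone). At a median of 0.18, the camera adjusted p was 0.00052 (adjusted p = 0.072 with an estimated correlation). Cyp51, the lanosterol demethylase, rose from 16.1 ± 0.517 to 21.4 ± 0.487 FPKM. Of 30 genes of G1 to S and replication, 4 rose and 0 fell in limma (4 and 0 adjusted over the list alone). The list's median was 0.09 and its camera adjusted p 0.0088 (adjusted p = 0.66 with an estimated correlation). Cyclin E1 (Ccne1) rose from 10.8 ± 0.651 to 16.5 ± 2.18 FPKM. The G1 to S and replication call was lost without PIF replicate 2, at an adjusted p of 0.47.

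Camera with the preset correlation also called 4 lists in PIF of which limma called 0 to 5 members each. Of the 15 mitochondrially encoded genes, limma called 0 (3 higher at an unadjusted p under 0.05, and 0 called with voom). The list had a median of 0.27 and a camera adjusted p of 0.014 (adjusted p = 0.66 with an estimated correlation), and without PIF replicate 3 the adjusted p was 0.38. The mitochondrially encoded share of reads was 0.517 ± 0.0254% in TB, 0.617 ± 0.120% in PIF, 0.491 ± 0.0576% in DIF and 0.579 ± 0.0512% in Met. Of 48 cytosolic ribosomal proteins, 1 fell (0 adjusted over the list alone). The median log2 change was −0.12, with a camera adjusted p of 0.00042 (adjusted p = 0.66 with an estimated correlation), and quantile normalization ended that call at 0.36. Of 41 genes of oxidative phosphorylation, 2 fell (0 adjusted over the list alone). Camera gave this list, at a median of −0.08, an adjusted p of 0.0027 (adjusted p = 0.66 with an estimated correlation), and without PIF replicate 3 the adjusted p was 0.098 and with quantile normalization 0.09. Of 20 heat shock and immediate early genes, 5 fell (6 adjusted over the list alone). At a median of −0.18, the camera adjusted p was 0.035 (adjusted p = 0.66 with an estimated correlation). That list lost its call without TB replicate 2 (adjusted p 0.056), PIF replicate 1 (0.051) or PIF replicate 3 (0.19), with quantile normalization (0.09) and with a filter at a mean FPKM of 2 (0.052). Dusp1, a phosphatase of MAP kinases and an immediate early gene, fell from 27.8 ± 1.2 to 18.0 ± 1.13 FPKM.

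In the other lists single genes moved in PIF without a list call. Among collagens and matrix, 3 of 45 rose and 10 fell (4 and 10 adjusted over the list alone; camera adjusted p 0.26), and biglycan (Bgn) fell from 61.6 ± 2.56 to 33.1 ± 3.85 FPKM. Among matrix proteases and inhibitors, 7 of 31 rose and 4 fell (7 and 4 adjusted over the list alone; camera adjusted p 0.12). In the TGF-beta pathway 6 of 29 rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p 0.068). Of 13 melanocyte differentiation genes, 3 rose and 1 fell (4 and 3 adjusted over the list alone; camera adjusted p 0.16), and Gpnmb rose by 0.85 on the log2 scale (SE 0.10). Integrins and focal adhesions gave 5 up and 5 down of 29 (5 and 5 adjusted over the list alone; camera adjusted p 0.98), and the integrin Itgb7 rose by 1.69 (SE 0.13). The dedifferentiated and invasive melanoma state gave 4 up and 3 down of 28 (5 and 3; camera adjusted p 0.94) and NF-kappaB and cytokines 4 up and 3 down of 22 (5 and 3; 0.13). JAK-STAT3 signalling gave 3 up and 1 down of 18 (5 and 2; 0.41), the interferon response 3 up and 1 down of 23 (3 and 1; 0.76), p53 targets 2 up and 1 down of 24 (1 and 1; 0.83) and chromatin modifiers 3 up and 6 down of 43 (5 and 6; 0.71). The median and the mean differed in sign for integrins and focal adhesions (−0.02 and 0.08), the dedifferentiated state (−0.09 and 0.04) and the interferon response (−0.07 and 0.01).

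DIF against TB asked the same question for DIF cells. Genes higher in DIF included osteoglycin (Ogn; 6.69 ± 0.831 against 0.0520 ± 0.0260 FPKM), Htra1 (log2 fold change 3.80, SE 0.16) and the basement membrane collagens Col4a1 (7.80 ± 1.86 against 0.845 ± 0.126 FPKM) and Col4a2 (4.07 ± 0.816 against 0.539 ± 0.0396). The annotated ends of Col4a1 and Col4a2 overlap, and the strand setting of the read assignment is not given. Cav1, the caveolar coat protein, rose from 0.204 ± 0.0680 to 3.48 ± 0.530 FPKM. Genes lower in DIF included Gpnmb (log2 fold change −3.45, SE 0.10), galectin 3 (Lgals3; 33.0 ± 11.6 against 315 ± 7.16 FPKM), kappa casein (Csn3; 3.05 ± 0.792 against 29.4 ± 2.40) and the cytokine Il33 (14.1 ± 2.03 against 68.6 ± 2.26). limma called 1091 genes (8.62%), 539 higher and 552 lower, with Benjamini-Hochberg adjusted p of 5.9e-08 for Htra1, 1.1e-05 for Col4a1 and 1e-08 for Gpnmb. A 2-fold change was reached by 136 of them, 82 higher and 54 lower, and the median size was 0.44. The count was 611 without TB replicate 2, 606 without TB replicate 3 and 589 without DIF replicate 2.

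Camera with the preset correlation called the matrix and TGF-beta lists higher in DIF. Beside these lists, the summed FPKM of Col1a1, Col1a2, Dcn and Lum, which fibroblasts hold in abundance, was 0.543 ± 0.406 in DIF and 0.123 ± 0.0419 in TB, and that of the 18 fibroblast markers 131 ± 2.70 and 106 ± 3.06. Of 45 genes of collagens and matrix, 14 rose and 1 fell (19 and 2 adjusted over the list alone). The list's median was 0.30 and its camera adjusted p 3.4e-08 (adjusted p = 0.54 with an estimated correlation). Bgn rose from 61.6 ± 2.56 to 142 ± 13.4 FPKM and the lysyl oxidase Loxl3 from 8.94 ± 0.936 to 20.3 ± 3.21. In the TGF-beta pathway 7 of 29 rose and 0 fell in limma (10 and 0 adjusted over the list alone). The list had a median of 0.18 and a camera adjusted p of 1.4e-05 (adjusted p = 0.20 with an estimated correlation). Id3, a BMP and TGF-beta response gene, rose from 83.9 ± 4.94 to 147 ± 8.60 FPKM, and the ligand Tgfb3 from 10.1 ± 0.498 to 15.8 ± 0.570. Of 26 MRTF and SRF targets, 4 rose and 1 fell (6 and 2 adjusted over the list alone). The median log2 change was 0.15, with a camera adjusted p of 0.031 (adjusted p = 0.58 with an estimated correlation). The call for MRTF and SRF targets was lost without TB replicate 3 (adjusted p 0.11), DIF replicate 2 (0.094) or DIF replicate 3 (0.094), with a filter at a mean FPKM of 2 (0.058) and with GC and length trends removed (0.084). Acta2 rose by 1.29 (SE 0.19), and zyxin (Zyx), a focal adhesion protein, from 129 ± 11.3 to 177 ± 6.31 FPKM. Of 23 interferon response genes, 8 rose and 0 fell in limma (12 and 2 adjusted over the list alone). Camera gave this list, at a median of 0.27, an adjusted p of 7.4e-06 (adjusted p = 0.14 with an estimated correlation). Isg15 rose from 5.24 ± 1.05 to 11.6 ± 1.81 FPKM and Bst2, or tetherin, from 18.5 ± 2.69 to 39.1 ± 1.10. Beside this list, summed leukocyte markers were 1.78 ± 0.332 FPKM in DIF and 2.85 ± 0.605 in TB.

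Lists of pigment cell, cell cycle, amino acid response and metabolic genes were called lower in DIF by camera with the preset correlation. Of 13 melanocyte differentiation genes, 7 fell and 0 rose in limma (7 and 0 adjusted over the list alone). At a median of −0.29, the camera adjusted p was 1.8e-06 (adjusted p = 0.055 with an estimated correlation). Mitf, the master transcription factor of melanocytes (chromosome 6, 97784013 to 97998310, plus strand), fell from 15.2 ± 0.622 to 4.24 ± 1.17 FPKM. Of 34 genes of G2 and mitosis, 11 fell and 0 rose in limma (22 and 0 adjusted over the list alone). The list's median was −0.22 and its camera adjusted p 2e-10 (adjusted p = 0.26 with an estimated correlation). Of 30 genes of G1 to S and replication, 2 fell and 0 rose in limma (9 and 0 adjusted over the list alone). The list had a median of −0.18 and a camera adjusted p of 8.9e-07 (adjusted p = 0.54 with an estimated correlation). Cyclin E2 (Ccne2) fell from 13.8 ± 0.928 to 9.96 ± 1.08 FPKM. Of 30 genes of the ATF4 and unfolded protein response, 9 fell and 1 rose (15 and 1 adjusted over the list alone). The median log2 change was −0.29, with a camera adjusted p of 3.9e-08 (adjusted p = 0.26 with an estimated correlation). Asparagine synthetase (Asns) fell from 96.9 ± 5.29 to 61.9 ± 5.70 FPKM, and the gene that rose was Ddit4, an inhibitor of mTORC1 signalling (12.7 ± 0.274 to 38.7 ± 3.59 FPKM). Of 23 genes of cholesterol synthesis, 3 fell and 0 rose in limma (7 and 0 adjusted over the list alone). Camera gave this list, at a median of −0.10, an adjusted p of 0.0024 (adjusted p = 0.070 with an estimated correlation). Of 41 genes of oxidative phosphorylation, 1 fell (0 adjusted over the list alone). At a median of −0.08, the camera adjusted p was 0.012 (adjusted p = 0.71 with an estimated correlation). The oxidative phosphorylation call was lost without TB replicate 3 (adjusted p 0.11) or DIF replicate 1 (0.23), with quantile normalization (0.52) and with GC and length trends removed (0.14).

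The remaining lists were not called in DIF. Actomyosin contractility gave 6 up and 2 down of 47 (9 and 3 adjusted over the list alone; camera adjusted p 0.20), and Myl9, at 205 ± 25.7 FPKM, missed the threshold (adjusted p 0.084 in limma). The log2 fold change of Myl9, DIF against TB, was called with quantile normalization (adjusted p 0.031), with voom (0.035), with GC and length trends removed (0.035) and with the spread of these groups alone (0.020). YAP and TEAD targets gave 5 up and 2 down of 21 (6 and 2; 0.064), and Ankrd1 rose from 1.52 ± 0.186 to 4.49 ± 0.239 FPKM. Integrins and focal adhesions gave 5 up and 1 down of 29 (5 and 2; 0.069), matrix proteases and inhibitors 6 up and 4 down of 31 (6 and 6; 0.48) and the dedifferentiated and invasive melanoma state 4 up and 2 down of 28 (7 and 5; 0.31). NF-kappaB and cytokines gave 3 up and 3 down of 22 (4 and 3; 0.82), and the chemokine Ccl2 fell from 14.4 ± 0.312 to 3.57 ± 0.671 FPKM. JAK-STAT3 signalling gave 5 up and 2 down of 18 (6 and 2; 0.15), with Stat3 itself rising from 9.81 ± 0.615 to 15.3 ± 1.51 FPKM. Hypoxia and glycolysis gave 1 up and 6 down of 29 (1 and 6; 0.59), p53 targets 1 up and 2 down of 24 (1 and 3; 0.71) and chromatin modifiers 1 up and 2 down of 43 (1 and 2; 0.19). Among heat shock and immediate early genes 1 of 20 rose and 2 fell (4 and 4; 0.54). limma called 0 of the 48 cytosolic ribosomal proteins (1 lower at an unadjusted p under 0.05; camera adjusted p 0.17) and 0 of the 15 mitochondrially encoded genes (0 at an unadjusted p under 0.05; camera adjusted p 0.36), and voom called 0 in both. The median and the mean differed in sign for NF-kappaB and cytokines (0.05 and −0.14) and for hypoxia and glycolysis (0.01 and −0.02).

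Met against TB asked what distinguished cells from lung metastases. Met cells held more RNA of Gatm, the first enzyme of creatine synthesis (chromosome 2, 122424948 to 122441784, minus strand), at 24.6 ± 0.238 against 3.67 ± 0.195 FPKM. The homeobox gene Meox1 rose from 0.111 ± 0.0739 to 7.39 ± 1.33 FPKM, the growth factor Fgf7 from 0.485 ± 0.0720 to 6.74 ± 1.66 and the ligand Bmp2 from 2.13 ± 0.280 to 14.7 ± 1.18. Csn3 fell from 29.4 ± 2.40 to 0.905 ± 0.0781 FPKM, apolipoprotein E (Apoe) from 18.3 ± 0.574 to 1.01 ± 0.291 and Gpnmb by 3.64 on the log2 scale (SE 0.10). limma called 1259 genes (9.94%), 673 higher and 586 lower, with Benjamini-Hochberg adjusted p of 2e-09 for Gatm, 5.9e-08 for Bmp2 and 1e-08 for Apoe. A 2-fold change was reached by 152, 88 higher and 64 lower, and the median size was 0.48. The count was 800 without TB replicate 2, 793 without TB replicate 3 and 810 without Met replicate 3.

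In the TGF-beta pathway 13 of 29 genes rose in Met and 0 fell in limma (16 and 0 adjusted over the list alone). The list's median was 0.40 and its camera adjusted p 1.4e-10 (adjusted p = 0.12 with an estimated correlation). Tgfbi, a TGF-beta induced matrix protein, rose from 13.8 ± 1.01 to 30.5 ± 1.35 FPKM, Thbs1 from 0.702 ± 0.0899 to 3.87 ± 0.542 and Id3 from 83.9 ± 4.94 to 153 ± 6.91. Of 45 genes of collagens and matrix, 15 rose and 4 fell (20 and 5 adjusted over the list alone). The list had a median of 0.25 and a camera adjusted p of 9.7e-05 (adjusted p = 0.72 with an estimated correlation). Beside this list, the summed FPKM of Col1a1, Col1a2, Dcn and Lum was 0.943 ± 0.361 in Met and 0.123 ± 0.0419 in TB, and that of the 18 fibroblast markers 116 ± 1.44 and 106 ± 3.06. The lysyl oxidase Loxl1 rose from 2.87 ± 0.481 to 8.23 ± 0.332 FPKM and Col18a1 from 26.1 ± 1.74 to 54.3 ± 7.25. Of 21 YAP and TEAD targets, 6 rose and 0 fell in limma (8 and 1 adjusted over the list alone). The median log2 change was 0.18, with a camera adjusted p of 0.00089 (adjusted p = 0.45 with an estimated correlation). Crim1 rose by 0.46 (SE 0.09) and Asap1 by 0.34 (SE 0.07). Of 13 melanocyte differentiation genes, 4 fell and 0 rose in limma (4 and 0 adjusted over the list alone). Camera gave this list, at a median of −0.17, an adjusted p of 0.00089 (adjusted p = 0.15 with an estimated correlation). Mitf was at 4.25 ± 0.827 FPKM and fell by 1.63 (SE 0.17), and the melanocortin receptor Mc1r fell from 0.746 ± 0.0453 to 0.130 ± 0.0374. Of 30 genes of the ATF4 and unfolded protein response, 12 fell and 1 rose (19 and 1 adjusted over the list alone). At a median of −0.28, the camera adjusted p was 2.8e-07 (adjusted p = 0.45 with an estimated correlation). Phgdh, the first enzyme of serine synthesis, fell from 103 ± 6.52 to 64.0 ± 5.83 FPKM, and Ddit4 rose by 1.09 (SE 0.11).

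Of 41 genes of oxidative phosphorylation limma called 0 (8 lower at an unadjusted p under 0.05, and 1 called with voom). The list's median was −0.10 and its camera adjusted p 0.00089 (adjusted p = 0.72 with an estimated correlation), and quantile normalization (0.15) and removal of GC and length trends (0.051) ended that call. Of 48 cytosolic ribosomal proteins limma called 0 (9 lower at an unadjusted p under 0.05, and 0 called with voom). The list had a median of −0.14 and a camera adjusted p of 5.7e-06 (adjusted p = 0.72 with an estimated correlation), and quantile normalization ended that call (0.33). Actomyosin contractility gave 4 up and 2 down of 47 in Met (4 and 3 adjusted over the list alone; camera adjusted p 0.48), and the myosin light chain kinase Mylk rose from 1.56 ± 0.0326 to 3.12 ± 0.254 FPKM. MRTF and SRF targets gave 2 up and 0 down of 26 in limma (2 and 0; 0.49). Integrins and focal adhesions gave 5 up and 0 down of 29 in limma (6 and 0; 0.10), and Itgb3 rose from 1.95 ± 0.141 to 5.33 ± 0.927 FPKM. Matrix proteases and inhibitors gave 7 up and 8 down of 31 (9 and 8; 0.90), with cathepsin B (Ctsb) falling from 270 ± 4.60 to 187 ± 9.20 FPKM. The dedifferentiated and invasive melanoma state gave 4 up and 2 down of 28 (7 and 4; 0.18), NF-kappaB and cytokines 2 up and 3 down of 22 (4 and 3; 0.48) and JAK-STAT3 signalling 3 up and 2 down of 18 (4 and 2; 0.16). In the interferon response 0 of 23 rose in limma and 3 fell (0 and 4; 0.063). Of 34 genes of G2 and mitosis limma called 0 (3 higher at an unadjusted p under 0.05, and 1 called with voom; camera adjusted p 0.082), and of 30 genes of G1 to S and replication 2 fell (1 adjusted over the list alone; 0.082). Hypoxia and glycolysis gave 2 up and 3 down of 29 (3 and 4; 0.87), cholesterol synthesis 1 down of 23 (1 adjusted over the list alone; 0.48) and p53 targets 1 up and 1 down of 24 (1 and 1; 0.90). limma called 0 of 43 chromatin modifiers (9 higher and 1 lower at an unadjusted p under 0.05, 2 and 1 called with voom; camera adjusted p 0.12) and 0 of 15 mitochondrially encoded genes (0 at an unadjusted p under 0.05 and 0 with voom; 0.14). Heat shock and immediate early genes gave 2 up and 2 down of 20 (2 and 3; 0.48). The median and the mean differed in sign for actomyosin contractility (−0.05 and 0.01), matrix proteases and inhibitors (−0.02 and 0.02), NF-kappaB and cytokines (0.01 and −0.15) and hypoxia and glycolysis (−0.01 and 0.13), and p53 targets had a median of 0.04 with a downward test. The number of lists called in Met was 7, against 12 with no filter, 11 without TB replicate 1, 11 with the spread of these groups alone and 4 with fry. In PIF it was 11 (7 with fry) and in DIF 10, and with an estimated correlation camera called 0 lists in each of the 3 comparisons with TB (3, 4 and 2 lists at an unadjusted p under 0.05 in PIF, DIF and Met). Cholesterol synthesis had an estimated correlation of −0.011, below the preset 0.01. Its camera adjusted p still went from 0.00052 to 0.072 in PIF and from 0.0024 to 0.070 in DIF. A higher correlation therefore does not account for the loss of those calls. Mixed splits of the libraries gave up to 14, 11 and 10 lists with the preset correlation, as given at the end.

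**Figure D2:**
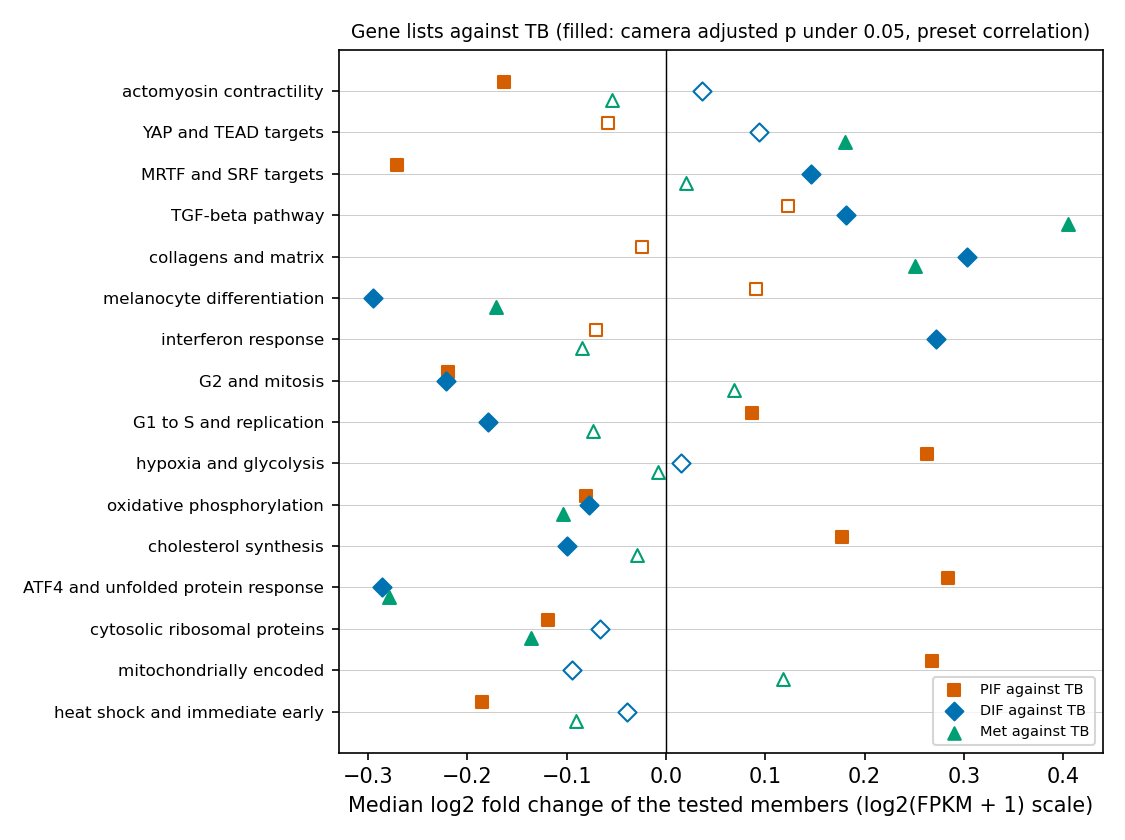
The median log2 fold change of the tested members is plotted for the gene lists called in at least 1 comparison with TB, with 1 symbol per comparison, filled where the camera adjusted p with the preset correlation was under 0.05. The ATF4 and unfolded protein response list lies at 0.28 in PIF, −0.29 in DIF and −0.28 in Met.

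Comparing DIF with PIF set the groups that stood farthest apart on component 1 side by side. Acta2 was higher in DIF by 2.61 on the log2 scale (SE 0.19) and Fhl1, a LIM domain protein of muscle and stress fibres, by 2.12 (48.3 ± 8.91 against 10.4 ± 2.61 FPKM). The interstitial collagenase gene Mmp1a was lower in DIF (5.27 ± 0.418 against 62.2 ± 6.03 FPKM), as was Gpnmb (log2 fold change −4.30, SE 0.10). limma called 2390 genes (18.9%), 1143 higher and 1247 lower, 239 of them by at least 2-fold (94 and 145), and 1497 with the spread of these groups alone. The Benjamini-Hochberg adjusted p was 2.9e-06 for Acta2 and 1.8e-09 for Mmp1a. In the ATF4 and unfolded protein response 28 of 30 genes were lower in DIF and 1 higher (28 and 1 adjusted over the list alone; median −0.63, camera adjusted p 4.7e-19, and adjusted p = 0.076 with an estimated correlation). In cholesterol synthesis 14 of 23 were lower and 0 higher in limma (16 and 0 adjusted over the list alone; median −0.27, camera adjusted p 1.3e-07), and this call held with an estimated correlation (adjusted p = 0.0061). Of 26 MRTF and SRF targets 14 were higher and 1 lower (16 and 1; median 0.35, 2.2e-07, and adjusted p = 0.17 with an estimated correlation), and of 47 actomyosin genes 17 were higher and 2 lower (22 and 2; median 0.20, 6.3e-07, and adjusted p = 0.17 with an estimated correlation). Of 45 genes of collagens and matrix 21 were higher and 2 lower (24 and 2; median 0.47, 2.3e-08, and adjusted p = 0.44 with an estimated correlation). The other calls with DIF lower were G1 to S and replication (median −0.26, camera adjusted p 6.6e-09), hypoxia and glycolysis (−0.20, 3.4e-05), melanocyte differentiation (−0.27, 2e-05) and mitochondrially encoded genes (−0.37, 0.0021), with an adjusted p of 0.36, 0.19, 0.052 and 0.61 with an estimated correlation. The interferon response was higher in DIF (median 0.30, camera adjusted p 0.00031, and adjusted p = 0.17 with an estimated correlation). The other 13 of the 23 lists were not called.

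Comparing Met with PIF gave the same order for several of these genes. Gpnmb was lower in Met by a log2 fold change of −4.49 (SE 0.10), Csn3 by −4.33 (SE 0.12) and Basp1, a membrane protein of neurons, by −3.44 (1.97 ± 0.585 against 30.8 ± 2.24 FPKM). Gatm was higher by 2.67 (SE 0.07) and Meox1 by 2.97 (SE 0.12). limma called 2234 genes (17.6%), 1120 higher and 1114 lower, 192 of them by at least 2-fold (82 and 110), with Benjamini-Hochberg adjusted p of 5e-10 for Gpnmb and 6e-10 for Gatm. In the ATF4 and unfolded protein response 26 of 30 genes were lower and 1 higher (26 and 1 adjusted over the list alone; median −0.64, camera adjusted p 2.9e-20, and adjusted p = 0.083 with an estimated correlation). Of 23 genes of cholesterol synthesis 8 were lower and 0 higher in limma (11 and 0; median −0.21, 8.4e-05), which held with an estimated correlation (adjusted p = 0.039). Of 34 genes of G2 and mitosis 24 were higher and 0 lower in limma (27 and 0; median 0.29, 3.4e-13, and adjusted p = 0.19 with an estimated correlation). The TGF-beta pathway (median 0.16, camera adjusted p 2.8e-05), collagens and matrix (0.38, 1.4e-06), MRTF and SRF targets (0.27, 5.2e-06), actomyosin contractility (0.15, 0.00024) and YAP and TEAD targets (0.27, 0.0013) were also higher, with an adjusted p of 0.19, 0.46, 0.19, 0.25 and 0.25 with an estimated correlation. Hypoxia and glycolysis (−0.21, 8.4e-05), melanocyte differentiation (−0.19, 0.00029) and G1 to S and replication (−0.15, 7e-05) were lower, with an adjusted p of 0.22, 0.083 and 0.48 with an estimated correlation.

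Comparing Met with DIF, the closest pair, Gatm was higher in Met by 2.43 on the log2 scale (SE 0.07), the surface protein Cd24a by 1.99 (138 ± 11.9 against 34.0 ± 4.53 FPKM), the angiopoietin Angpt2 by 1.92 (6.37 ± 0.197 against 0.959 ± 0.187) and Bmp2 by 1.81 (SE 0.10). Lower in Met were Apoe (log2 fold change −1.79, SE 0.11), the galectin 3 binding protein Lgals3bp (2.06 ± 0.393 against 9.76 ± 0.616 FPKM) and Isg15 (3.22 ± 0.654 against 11.6 ± 1.81). limma called 489 genes (3.86%), 299 higher and 190 lower, 48 of them by at least 2-fold (26 and 22), with Benjamini-Hochberg adjusted p of 3.5e-09 for Gatm and 0.00041 for Isg15. The count was 286 without DIF replicate 1, 277 without DIF replicate 2, 257 without Met replicate 2, 234 without Met replicate 3 and 300 with the spread of these groups alone. In the interferon response 7 of 23 genes were lower in Met and 0 higher in limma (13 and 0 adjusted over the list alone; median −0.34, camera adjusted p 5.9e-12), which held with an estimated correlation (adjusted p = 0.046). In G2 and mitosis 12 of 34 were higher and 0 lower in limma (29 and 0 adjusted over the list alone; median 0.27, camera adjusted p 1.3e-20, and adjusted p = 0.12 with an estimated correlation). The TGF-beta pathway (median 0.19, camera adjusted p 0.00016), G1 to S and replication (0.13, 0.00097), cholesterol synthesis (0.10, 0.0043) and mitochondrially encoded genes (0.23, 0.0043) were higher, with an adjusted p of 0.27, 0.83, 0.086 and 0.83 with an estimated correlation. Cytosolic ribosomal proteins (−0.09, 0.00025) and actomyosin contractility (−0.07, 0.022) were lower, both with an adjusted p of 0.83 with an estimated correlation.

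**Figure D3:**
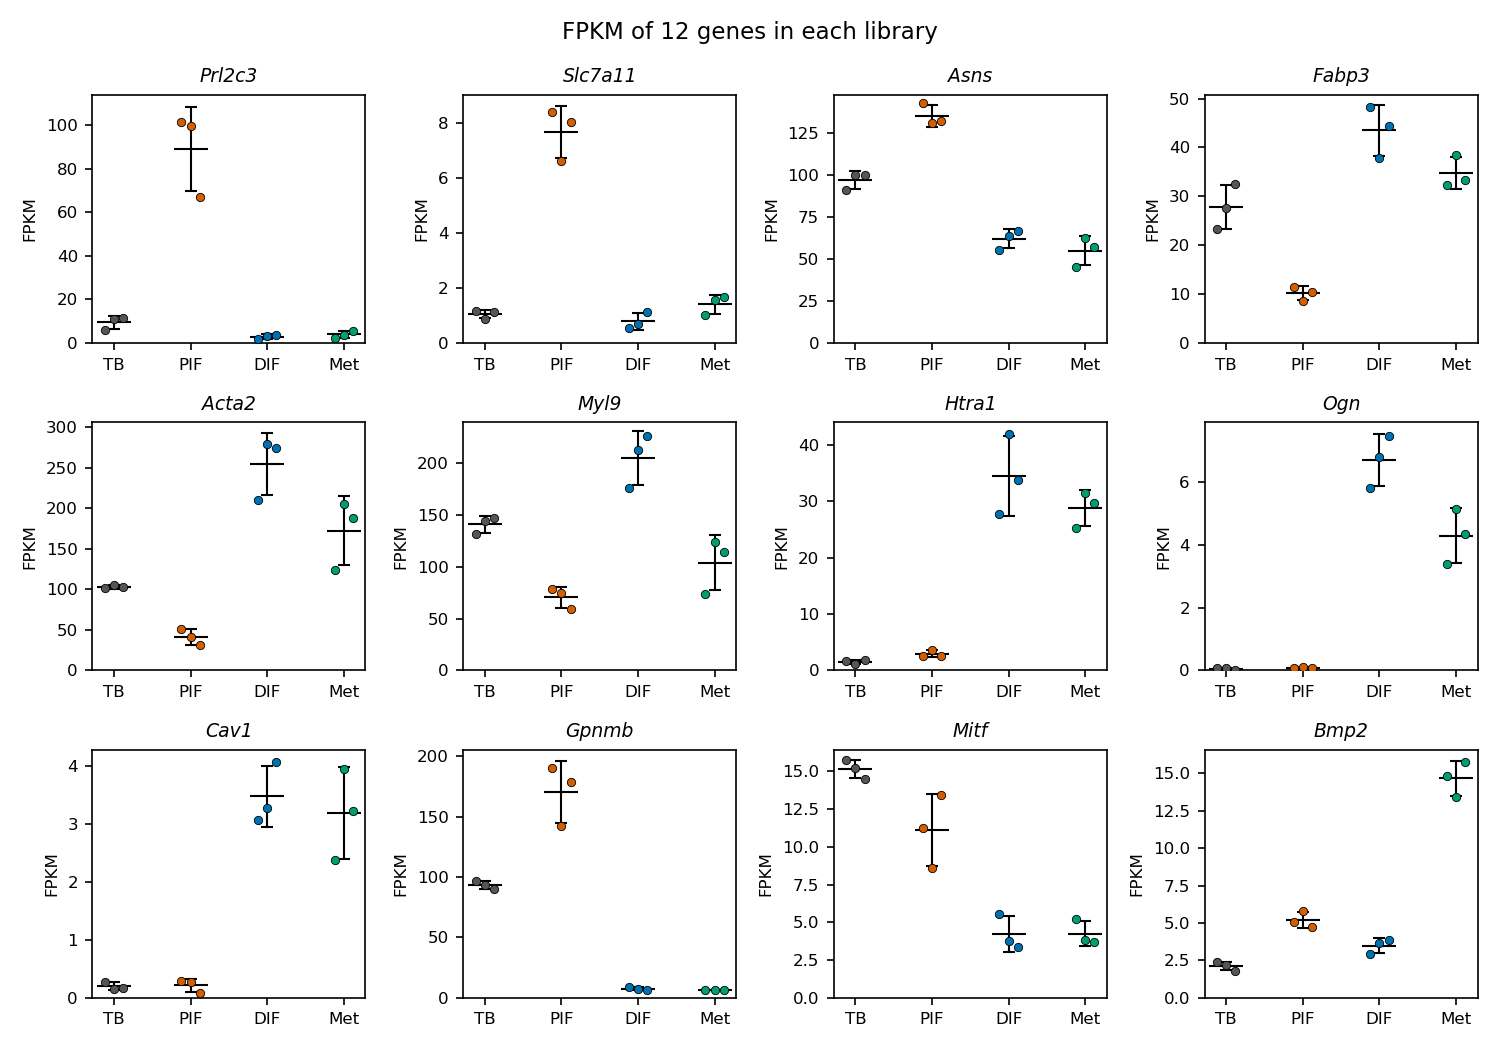
FPKM of 12 genes in each library, with points for the 3 libraries of each group and bars for the mean and SD. Slc7a11 is at 7.66 ± 0.943 FPKM in PIF, Acta2 at 255 ± 38.3 in DIF, and Mitf at 4.24 ± 1.17 in DIF and 4.25 ± 0.827 in Met.

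Some genes moved away from TB in the same direction in PIF, DIF and Met. Osteopontin (Spp1), a secreted phosphoprotein of bone and tumours, was at 381 ± 30.0 FPKM in TB, 700 ± 63.4 in PIF, 1092 ± 211 in DIF and 1203 ± 175 in Met. The aldehyde dehydrogenase Aldh3a1 rose by 1.37, 1.10 and 2.50 on the log2 scale (SE 0.18) in PIF, DIF and Met. Apoe (−1.24, −1.48 and −3.27, SE 0.11), the Wnt antagonist Dkk2 (−0.94, −0.69 and −1.67, SE 0.08) and Bean1 (−0.97, −1.34 and −1.61, SE 0.09) fell in all 3. In total 83 genes were called higher and 62 lower in all 3 comparisons. Independent sets of these sizes would share 2.15 and 1.68. The 3 comparisons share the TB libraries, and without TB replicate 2, TB replicate 3 or DIF replicate 2 the total of 145 became 58, 57 or 83. With no filter it was 95 (40 higher and 55 lower). DIF and Met shared 311 higher and 283 lower calls (28.7 and 25.5 expected of independent sets) and 12 in opposite directions (54.3 expected). PIF and DIF shared 106 higher and 122 lower calls (40.5 and 36.3 expected) and 174 in opposite directions (77.0 expected), and PIF and Met 194, 152 and 129 (50.6, 38.6 and 88.3 expected). Across genes the fold changes against TB correlated at r = 0.70 for DIF and Met, 0.29 for PIF and Met and 0.14 for PIF and DIF, where 20 simulated sets of unchanged groups that share the TB libraries gave 0.50 in each case. The covariances of these fold changes were 0.0571, 0.0233 and 0.0106 in the same order, and 0.0105, 0.0106 and 0.0105 in the simulated sets. The simulated sets gave every group the same spread per gene. Mean correlations between libraries were 0.992 within TB, 0.988 within PIF, 0.990 within DIF and 0.991 within Met. TB may thus vary less than simulated, and the simulated values may be too high. The 3 pairs of comparisons that share no library correlated across genes at r = 0.50 (DIF against TB with Met against PIF), 0.32 (Met against TB with DIF against PIF) and 0.21 (PIF against TB with Met against DIF), and at 0.25, 0.14 and 0.13 by ranks.

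Genes of the cytoskeleton and of melanoma state that were fixed for report showed small differences apart from those given above and from Myl9 in Met. Myl9 was at 132, 144 and 147 FPKM in the 3 TB libraries and at 73.8, 124 and 115 in the 3 Met libraries. Nonmuscle myosin heavy chain Myh9 was at 84.2 ± 11.6 FPKM in TB, 87.0 ± 8.58 in PIF, 94.3 ± 4.92 in DIF and 87.7 ± 1.59 in Met, and was not called in limma. Rhoa was at 95.6 ± 0.146, 85.7 ± 4.80, 86.8 ± 4.16 and 84.1 ± 4.13 FPKM in the same order, Rock1 at 2.89, 3.16, 2.94 and 3.26 and Rock2 at 12.6, 12, 12 and 12.8, none of them called against TB. Rhoc was at 508 ± 17.8 FPKM in DIF and 475 ± 13.4 in Met. Its Benjamini-Hochberg adjusted p against TB in limma was 0.049 and 0.0052. The log2 fold change of Rhoc, DIF against TB, was not called without any 1 of the 6 TB and DIF libraries (adjusted p 0.057 to 0.16), with no filter (0.137), with the spread of these groups alone (0.0981) or with quantile normalization (0.195), and the log2 fold change of Rhoc, Met against TB, was not called with quantile normalization (0.089). Sox10, a neural crest transcription factor, was at 230 FPKM in TB, 249 in PIF, 221 in DIF and 217 in Met, the receptor Ngfr at 159, 192, 132 and 138 and the receptor kinase Axl at 130, 136, 126 and 145, none of them called against TB in limma. The log2 fold change of Ngfr, PIF against TB, was called with a replicate block (adjusted p 0.0439), with voom (0.0414) and without TB replicate 1 (0.0408), and the log2 fold change of Mitf, PIF against TB, with voom (0.0488). The pigment enzymes Tyr (0 to 0.0268 FPKM) and Dct (0.00617 to 0.0999 FPKM) were under the filter in all 4 groups and were not tested. Mean Xist levels were 0.00210 to 0.0107 FPKM in the 4 groups, and the Y-linked genes Ddx3y (18.7 to 22.5 FPKM), Eif2s3y (7.89 to 9.25), Kdm5d (1.72 to 2.21) and Uty (2.70 to 3.46) were measured in every group.

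Markers of other cell types were measured beside the tumour genes. The 18 fibroblast markers summed to 106 ± 3.06 FPKM in TB, 97.9 ± 2.77 in PIF, 131 ± 2.70 in DIF and 116 ± 1.44 in Met, and most of each sum was Gsn, an actin filament severing protein, at 93.4 ± 2.62, 88.7 ± 1.61, 115 ± 3.11 and 106 ± 2.15 FPKM. The 22 leukocyte markers summed to 2.85 ± 0.605, 4.02 ± 0.535, 1.78 ± 0.332 and 1.90 ± 0.169 FPKM in the same order. The 15 endothelial markers summed to 3.69 ± 0.766, 3.31 ± 0.391, 6.32 ± 0.277 and 4.39 ± 0.313 FPKM, and Plvap, an endothelial vesicle protein, rose in DIF from 3.07 ± 0.701 to 5.90 ± 0.263, while Pecam1, Cdh5, Kdr and Tek together were at 0.0152 ± 0.0161 FPKM in TB and 0.0235 ± 0.0149 in DIF. The 20 lung epithelial markers summed to 1.25 ± 0.270, 1.35 ± 0.139, 2.62 ± 0.182 and 1.47 ± 0.630 FPKM, so the sum in Met cells, which came from lung, was under that in DIF. The 14 keratinocyte markers in the table summed to 5.57 ± 0.443, 6.28 ± 1.32, 4.53 ± 0.868 and 4.93 ± 0.292 FPKM, and 17 skeletal muscle and adipocyte markers to 1.99 ± 0.367, 1.58 ± 0.134, 1.43 ± 0.284 and 1.36 ± 0.120 FPKM.

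A pair of related noncoding loci, chosen after their values were seen, each stood far above the other groups in 1 group. Gm46223, a processed pseudogene (chromosome 10, 50298230 to 50298904, minus strand), was at 15.3 ± 2.68 FPKM in TB, 720 ± 139 in PIF, 0.0271 ± 0.0470 in DIF and 22.9 ± 3.26 in Met. Gm37416, a locus whose transcript awaits experimental evidence (chromosome 2, 16027919 to 16028236, minus strand), was at 12.3 ± 1.67, 15.2 ± 1.55, 16.8 ± 3.71 and 180 ± 12.1 FPKM in the same order. Their annotated transcripts share 97.1% of 315 aligned bases. The Benjamini-Hochberg adjusted p in limma was 2.5e-09 for Gm46223 in PIF against TB and 1.4e-08 for Gm37416 in Met against TB. Reads of such near-identical loci are uncertain in their origin.

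**Figure D4:**
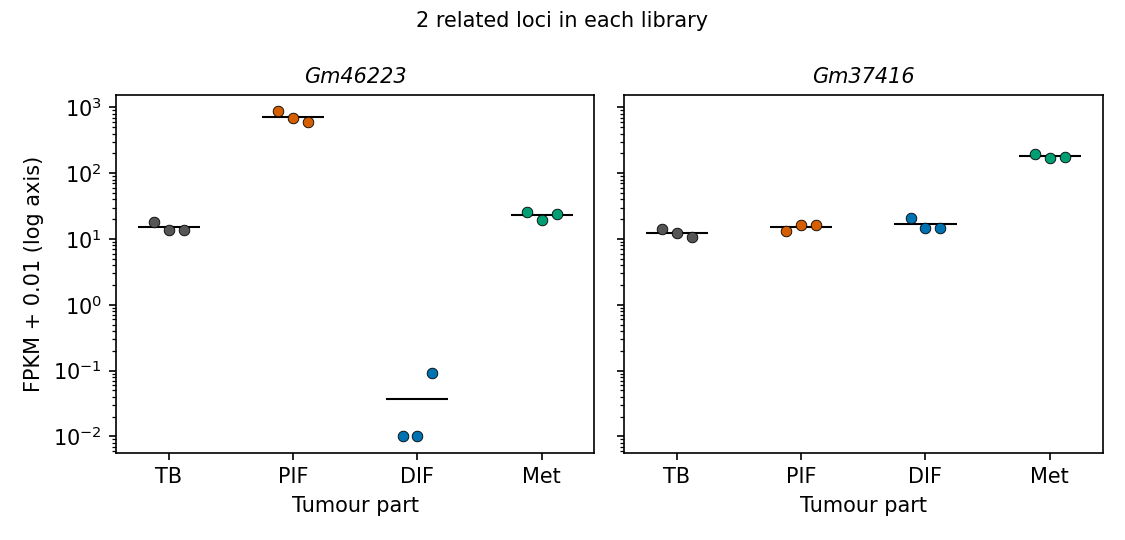
FPKM + 0.01 on a log axis of Gm46223 and Gm37416 in each of the 12 libraries, with points for libraries and lines for group means. Gm46223 is at 720 ± 139 FPKM in PIF and Gm37416 at 180 ± 12.1 FPKM in Met.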

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

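The tests on the Gm46223 and Gm37416 pair and the removal of GC and length trends were chosen only after the results were seen. Results are listed here because the effect in PIF and the effect in DIF or Met, both against TB, were each called (lists by camera with the preset correlation, genes by limma with at least a 2-fold change) on opposite sides of 0, and the difference between them was called as well.

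Among the lists, ATF4 and unfolded protein response genes were at a median log2 fold change against TB of 0.28 in PIF, −0.29 in DIF and −0.28 in Met, with direct differences of −0.63 (DIF against PIF, camera adjusted p 4.7e-19) and −0.64 (Met against PIF, 2.9e-20). With an estimated correlation these p-values were 0.076 and 0.083. The calls against TB were lost as well, at a camera adjusted p of 0.21 in PIF, 0.26 in DIF and 0.45 in Met with an estimated correlation. If a GC or length trend were the whole cause, the PIF median would have gone toward 0 once the trends were removed, but it was 0.31 (camera adjusted p 4.3e-14), and with the mitochondrial share of reads as a covariate it was 0.42 (2.6e-13). These values argue against both as the whole cause. A different response of cells from PIF to amino acid or folding stress may account for the pattern, and so may a difference in culture density, handling or medium between groups, which no table here measures.

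Gm46223 differed between DIF and PIF by a log2 fold change of −9.44 (5.46 in PIF and −3.97 in DIF against TB, adjusted p 4.5e-12 in limma; the 3 DIF libraries held 0, 0 and 1 rebuilt reads, so the fold depends on the added 1), and Gm37416, a related locus, was high in Met. If reads of 1 transcript had been divided between these loci in a fixed proportion, the 543 rebuilt reads of Gm46223 beside 206 of Gm37416 in TB would require 746 of Gm46223 beside the 283 of Gm37416 in DIF, but there was 1, a share of 0.00134. The loci were chosen for levels that already departed from a fixed proportion, so this count restates the pattern and is no separate test of such a division. If the chromosomal region around Gm46223 had been gained in PIF, its 4 tested neighbours within 2 Mb would be higher, but their median log2 fold change was −0.19 (−0.38 to −0.06). Of the annotated relatives of Gm46223, Gm42427 (99.7% identical over 673 bases) was at 0 to 0.0345 FPKM, Gm46620 (99.4% over 349) at 2.46 to 4.11 and AI506816 (92.3% over 338) at 25.1 to 35.3, highest in PIF, while Gm26880 was not in the table. A candidate source that stays open is a separate active copy in each group, such as a repeat or retrotransposed insertion absent from the annotation, and the reads themselves would be needed to place it.

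The other lists that met this rule were MRTF and SRF targets (difference 0.35, DIF against PIF, with −0.27 in PIF and 0.15 in DIF), G1 to S and replication (−0.26, with 0.09 and −0.18) and cholesterol synthesis (−0.27, with 0.18 and −0.10). The camera adjusted p of these differences was 2.2e-07, 6.6e-09 and 1.3e-07, and 0.17, 0.36 and 0.0061 with an estimated correlation. Against TB, camera with an estimated correlation gave MRTF and SRF targets an adjusted p of 0.21 in PIF and 0.58 in DIF. It gave G1 to S and replication 0.66 and 0.54, and cholesterol synthesis 0.072 and 0.070. As given above, the MRTF and SRF call in DIF and the G1 to S call in PIF were lost without single libraries. Among genes, Acta2 differed between DIF and PIF by 2.61 (−1.32 in PIF and 1.29 in DIF against TB). Prl2c2 differed by −4.56 between DIF and PIF and by −4.33 between Met and PIF, and Prl2c3 by −4.55 and −4.24. Mmp1a differed by −3.33 and −3.22, and Ngef by −2.67 and −2.24. Gm48479 differed by −2.81 and −2.56, Gm48480 by −2.72 and −2.17 and Tmem179 by −2.53 and −2.60 in the same order. Trib3, a pseudokinase induced by ATF4, differed between Met and PIF by −2.57 (1.39 in PIF and −1.18 in Met against TB).

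The 6 libraries of 2 groups can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split of DIF and PIF gave 2390 calls and the highest other split 0 in limma, and that of Met and PIF gave 2234 and 0. Every other split mixes the 2 groups and puts their difference into the spread, so low counts there are built in.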

How the results depend on the processing

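Removal of GC and length trends was chosen after seeing the data. No called gene changed sign under any alternative, and no alternative shifted the median of all genes by over 0.1. Median-ratio scaling divided every library by 1.0053 and changed the count in Met against TB from 1259 to 1260, so it says nothing about stability. The numbers of calls under quantile normalization, voom, the other pseudocounts, a mean FPKM of at least 2 and removal of GC and length trends stayed within 1.5 times those reported for all 6 comparisons and the F test. Of 461 pairs of a named gene and a comparison, 349 were called, and 290 changes from called to not called arose over all settings that left out 1 library, against 44 with no filter, 24 with only the 2 groups compared, 13 with quantile normalization, 10 with a replicate block, 8 with voom, 5 with a pseudocount of 0.1 and 2 with GC and length trends removed. Changes from not called to called numbered 22 with GC and length trends removed and 15 with voom. They numbered 15 with only the 2 groups compared, 15 over the settings that left out 1 library, 8 with a replicate block and 7 with quantile normalization.

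With only the 2 groups compared, calls were 1132 in PIF against TB, 1497 in DIF against PIF and 300 in Met against DIF, fewer than reported, but 1461 in Met against TB, more than reported. Without filter, genes called in 1 direction in all 3 comparisons with TB numbered 95, where more genes were tested. For gene lists, the number called in Met against TB was 12 with no filter, 11 with only the 2 groups compared, 4 with fry and 0 with an estimated correlation, in PIF against TB 7 with fry and 0 with an estimated correlation, and in DIF against TB 0 with an estimated correlation. fry asks whether the genes of a list move on balance in 1 direction, not whether they rank apart from other genes. The cause of these changes was not tested.

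Leaving out 1 library of the groups compared gave 958 to 1788 calls in PIF against TB, 589 to 950 in DIF against TB, 793 to 1102 in Met against TB, 1822 to 2232 in DIF against PIF, 1624 to 2298 in Met against PIF and 234 to 400 in Met against DIF. The F test called 2377 to 3118 genes, and 57 to 172 were called in 1 direction in all 3 comparisons with TB. Lists called numbered 8 to 12 in PIF, 8 to 13 in DIF and 7 to 11 in Met against TB.

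Replicate numbers were not shown to pair the samples. After group means were removed, correlations across genes between libraries of the same number were −0.20 to 0.33, 5 of 18 were above 0.1, and the best partner had the same number in 18 of 36 cases, where 12 would be expected and 24 of 216 relabelings within groups gave as many. The counts of genes called were all higher with the block, so a weak pairing stays open. A block for the replicate number gave 1901 calls in PIF against TB, 1226 in DIF against TB, 1317 in Met against TB, 2562 in DIF against PIF, 2342 in Met against PIF, 537 in Met against DIF, 3323 in the F test and 158 in all 3. Of 56748 genes, 27256 were above 0 in at least 1 library and 12661 passed the filter on mean FPKM. Genes under the filter were given no call, and the effect of depth was not tested.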

Other observations

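The tests of other cell types for the interferon pattern and the removal of GC and length trends were chosen only after the results were seen.

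Further named genes differed between tumour parts. The chemokine Ccl8 was at 4.23 ± 1.36 FPKM in TB, 4.66 ± 1.51 in PIF, 0.111 ± 0.108 in DIF and 0.0356 ± 0.0617 in Met, with a log2 fold change of −2.21 in DIF and −2.30 in Met against TB. Secretogranin 2 (Scg2), a granule protein of neuroendocrine cells, was at 46.7 ± 0.586, 65.2 ± 16.1, 9.47 ± 1.28 and 34.7 ± 1.73 FPKM in the same order, and fell by 2.19 (SE 0.14) in DIF against TB. Synaptotagmin 4 (Syt4) fell by 2.74 in DIF and by 3.04 in Met, and the NADPH oxidase Nox3 by 2.62 and 2.51. Rgs2, a regulator of G protein signalling, was at 7.69 ± 0.0555 FPKM in TB, 12.1 ± 1.03 in PIF, 0.806 ± 0.126 in DIF and 1.17 ± 0.278 in Met. Lat, an adaptor best known from T cells, went from 5.95 ± 0.585 FPKM in TB to 2.13 ± 0.425 in PIF, 0.0132 ± 0.0114 in DIF and 0.0725 ± 0.0115 in Met, while summed leukocyte markers were 2.85 ± 0.605, 4.02 ± 0.535, 1.78 ± 0.332 and 1.90 ± 0.169 FPKM. The N-cadherin gene Cdh2 rose in Met from 35.7 ± 2.50 to 51.8 ± 3.82 FPKM, and the metalloprotease inhibitor Timp3 from 16.5 ± 1.23 to 23.7 ± 1.43. The Notch target Hey1 rose in DIF from 0.528 ± 0.0978 to 4.97 ± 2.25 FPKM.

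Interferon response genes were higher in DIF than in TB (median log2 fold change 0.27, adjusted p = 0.14 with an estimated correlation) and lower in Met than in DIF (−0.34, adjusted p = 0.046). Leukocytes carried along in the DIF cultures would raise their markers in DIF, but summed FPKM of 22 leukocyte markers was lower in DIF than in TB by a difference of −1.07 (SE 0.398), while the interferon list, which leukocytes express in part, summed to 794 ± 19.0 FPKM in DIF and 752 ± 22 in TB. Of the leukocyte markers, 1 was above 1 FPKM in TB and 0 in DIF, so that difference lies near the floor. The full marker sums of fibroblasts, endothelium and lung epithelium did rise from TB to DIF (106 ± 3.06 to 131 ± 2.70, 3.69 ± 0.766 to 6.32 ± 0.277 and 1.25 ± 0.270 to 2.62 ± 0.182 FPKM). Such cells would bring all their abundant transcripts. Against the rise of 46.3 FPKM over the 8 interferon genes called higher in DIF, the sums in DIF were 0.543 ± 0.406 FPKM for Col1a1, Col1a2, Dcn and Lum of fibroblasts (a share of 0.0117), 0.0235 ± 0.0149 for Pecam1, Cdh5, Kdr and Tek of endothelium (0.000508) and 0.0854 ± 0.0607 for Sftpc, Sftpb, Scgb1a1 and Epcam of lung epithelium (0.00185). Those genes were chosen after their values were seen, while the full sums rose, so this test cannot decide on these 3 cell types. With GC and length trends removed the median in DIF was 0.28, which argues against such a trend as the whole cause. A lasting difference in interferon signalling of DIF cells may account for the pattern, and so may an exposure during isolation, which was not measured.

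Regrouping the 12 libraries at random into 4 groups of 3, with 100 groupings including the real one, gave as many genes past the F test in 1 of 100, the real grouping itself (3135, highest other 671). At this share a random grouping of 12 independent libraries can be excluded for that count. Whether the 3 libraries of a group came from different animals is not stated, so chance differences between single isolations cannot be excluded. Genes called in 1 direction in all 3 comparisons with TB were as many in 2 of 100 groupings, the real one (145) included, and the highest other gave 393. A regrouping that calls more than the real one points to a structure of the samples. In that grouping the 3 PIF libraries took the place of TB and the other 9 libraries were mixed over 3 groups. The next highest gave 54, and 95 of the 99 other groupings gave 0.

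The 6 libraries of 2 groups split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 1785 calls in PIF against TB, 1091 in DIF against TB, 1259 in Met against TB and 489 in Met against DIF, and the highest other split 0, 1, 2 and 0 in limma. As many calls arose in 1 of 10 splits each time, the real one. The other splits mix the 2 groups and put their difference into the spread, so their low counts of called genes are built in. For gene lists the real split gave 11 in PIF, 10 in DIF and 7 in Met against TB, and the highest other split 14, 11 and 10. As many lists arose in 4, 3 and 5 of the 10 splits, the real one included. The number of lists called with the preset correlation therefore did not set the real groups apart from mixed splits. A mixed split keeps part of the group difference, so its list calls do not measure false calls alone.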
